A study of Caenorhabditis elegans with 2 samples.

How the data were processed

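RNA from whole wild-type Caenorhabditis elegans hermaphrodites, aged 5 days and fed heat-killed Escherichia coli OP50 (the standard laboratory food bacterium), was sequenced in 2 libraries. The labels describe total RNA as the starting material and an Illumina mRNA preparation kit, and they place both libraries in the same group. There was therefore 1 group with 2 samples and no contrast between conditions. The replicates were numbered in accession order, so replicate 1 and replicate 2 are names only. Nothing in the labels says that the samples came from separate cultures, so the spread between them may be technical.

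Per the submitters' processing notes, reads were handled with STAR 2.4.1d and featureCounts 1.4.6-p4, and the genome build named is WBcel235. The counting options, the strand setting and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Genes with near-identical copies (vit-3, vit-4 and vit-5, the msp genes, the core histones, cyp-31A2 and cyp-31A3, the hsp-16 pairs) have uncertain counts for the same reason. The deposited table of raw counts per gene held 46748 WormBase gene identifiers, of which 46449 were in Ensembl release 115 of the same build and 43702 had a symbol. Identifiers outside that release held 0.173% and 0.169% of the counts in replicates 1 and 2. The 12 mitochondrial protein genes were named by their position in the RefSeq annotation (at least 90% overlap). Coordinates are those of the Ensembl annotation.

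The deposited RPKM values (reads per kilobase of gene, scaled to the read total of the library) were checked against the counts before use. How the authors computed RPKM is not given in the sources used here, but dividing counts by RPKM returns gene length times the read total used. That read total changed with the row number, repeating every 8 rows, and equalled the library's own total in 12.5% of rows. Over 5766 genes with more than 500 counts in both libraries, 100% lay within 0.1% of the ratio of their row class, and the ratio of replicate 1's total to replicate 2's ran from 0.787 to 1.27 between classes. Each deposited RPKM was therefore multiplied by the total that had been used and divided by the library's own total. After this rescaling, the gene lengths implied by both libraries matched within 0.5% for 100% of the 8572 genes with at least 100 counts in both. The totals had been estimated from the same counts and RPKM with annotated exon lengths. That match therefore checks the rescaling but is not independent support for it. RPKM below means the rescaled value. This departs from the plan, which took RPKM as deposited, and the deposited values were kept as an alternative.

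Total counts were 28164638 in replicate 1 and 31271070 in replicate 2. The floor of 3 counts corresponded to 0.107 and 0.0959 CPM (counts scaled to the library total, computed here from the deposited counts). Shares of counts were given 95% Wilson intervals. Intervals and floors cover counting error only. A gene was called detected with at least 10 counts in both libraries. Values are given as the mean ± SD of the 2 libraries (n = 2) unless stated otherwise. The median of a list is that of its members' mean RPKM, and its SD is that of the medians of the 2 libraries, so the median printed can lie outside the medians of both libraries. Differences between lists were likewise computed from mean RPKM, with the SD of the differences in the 2 libraries.

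Before the data were examined, 34 gene lists, 14 pairs of lists and the rule for named genes were fixed. For each list, the median RPKM of its detected members was placed among the medians of 10000 random lists of the same size drawn from all detected genes, and positions under the percentile 2.5 or over 97.5 were called low or high. About 5% of lists of genes drawn at random would fall there. Members of a real list are not drawn at random, so that share is not the rate for gene groups. Of 175 gene-name families examined later, 39 lay above and 39 below such limits. For each pair, the difference of mean log2(RPKM + 1) over every matched member was tested with a two-sided permutation test over genes (100000 permutations, or an exact enumeration where fewer existed), with Benjamini-Hochberg adjustment over the 14 pairs. Genes shared by a pair were left out. Genes are not independent replicates, so these p-values describe the lists in these libraries. The smallest p that 100000 permutations can give is 1e-05, or 2.8e-05 after adjustment.

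The libraries were compared gene by gene with a two-sided exact binomial test on the counts, for genes with at least 10 counts in the sum, using TMM effective library sizes from edgeR 4.0.16. Calls required a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold difference. That test holds counting noise only and compares 2 libraries of the same group, not conditions. Log2 ratios are replicate 2 over replicate 1, with 0.5 added to each count, and their 95% intervals are exact. List shifts were the median log2 ratio of the members, placed among 10000 random lists matched on mean expression in 20 bins. Here too, members of a real list are not drawn at random. To remove a trend with gene length, chosen after the data were seen, the median log2 ratio of each of 50 bins of annotated exon length was subtracted. On simulated data with such a trend, 76% of 50 lists of short genes fell outside the limits before subtraction and 8% after it. A gene at 0 counts in a library was set at the floor of 3 counts to give its fold. That fold leaves out the counting error of the other library. The common biological coefficient of variation was estimated in edgeR with an intercept alone, since a quasi-likelihood contrast cannot be fitted with 1 group.

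The rule for named genes took the 10 genes with the highest mean RPKM, the 2 highest and the lowest detected member of each list, and every member of lists with 6 or fewer. Between the libraries it took the 10 largest and 10 smallest ratios among called genes with a mean of at least 100 counts, and the called member with the largest change in each list. Only 7 genes in each direction met the mean of 100 counts. Of the genes the rule names, some are left out of the text. Genes named outside this rule, chosen after their values were seen, are ND2, qua-1, col-119, daf-2, daf-16, rol-1, hsp-16.41, sod-3, fat-6, fat-7, gst-4 and the genes and families of the closing section.

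On simulated counts for 14397 genes, with 200 genes changed between the libraries, the binomial test called 82% of 50 genes at a log2 ratio of -2, 86% at -1.5, 82% at 1.5 and 88% at 2, and it called 2 unchanged genes. Those counts held counting noise only, which the test assumes. The real libraries differed by more than that, so the simulation does not give the share of false calls among them. In simulated list tests on 14397 genes, 4.5% of random lists fell outside the limits and 5.6% of null pairs had p under 0.05. Alternatives covered the detection limit, the pseudocount, CPM in place of RPKM, other backgrounds, library totals and DESeq2 1.42.0 size factors in place of TMM, other count and fold minimums, and edgeR's exact test with an assumed coefficient of variation of 0.1 or 0.2. Every column of the deposited tables belonged to 1 of the 2 samples. Other tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.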

Results

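Messenger RNA was profiled in whole adult hermaphrodites of the wild-type C. elegans strain, aged 5 days and kept on heat-killed OP50 bacteria. The series title places these animals in work on how an OP50 diet relates to lifespan, and the libraries described here form its only group, with 2 replicates. Replicate 1 held 28164638 counts and replicate 2 held 31271070 counts. The comparisons below are between gene groups within the animals, and between the 2 libraries.

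With at least 10 counts in both libraries, 12757 genes were detected, of which 12268 were protein-coding and 329 were pseudogenes. Protein-coding genes held 97.0% of the counts in replicate 1 and 97.9% in replicate 2. The 10 most abundant genes of each library took 12.81% and 11.99% of its counts. Across the 14397 genes with at least 10 counts in the sum, log2(CPM + 1) of the libraries correlated with a Pearson r of 0.998 and a Spearman rho of 0.994. These are correlations across genes, which are not independent replicates. The common biological coefficient of variation was 0.0547. A chi-square test over the same genes gave 126979 on 14396 degrees of freedom, 8.82 per degree of freedom, so the libraries differed by more than sampling noise and were not the same library deposited again. Abundant genes weigh heavily in that sum, among them the ribosomal RNA gene rrn-3.1 (688425 and 496006 counts in replicates 1 and 2). The value of 8.82 is therefore not the spread of a typical gene.

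Yolk, translation and small heat shock protein transcripts headed the ranking. The translation elongation factor eef-1A.1 (WBGene00001168, chromosome III, 6970026 to 6971712) had the highest level, 7401 ± 90.5 RPKM. The yolk protein genes vit-6 (WBGene00006930, chromosome IV, 8261157 to 8266459; 6211 ± 0.371 RPKM), vit-5 (WBGene00006929, chromosome X; 4312 ± 103 RPKM) and vit-2 (WBGene00006926, chromosome X; 4134 ± 54.3 RPKM) were also among the 10 highest. So were sip-1, which encodes a small heat shock protein (5435 ± 80.7 RPKM), far-2, a fatty acid and retinol binding protein gene (2492 ± 173 RPKM), and the ribosomal protein genes rps-25 (3007 ± 108 RPKM), rpl-41.2 (2727 ± 524 RPKM) and rpl-10 (2333 ± 43.9 RPKM). The ribosomal RNA gene rrn-3.1 was listed at 6966 RPKM in replicate 1 and 4521 RPKM in replicate 2, the widest gap between the libraries within the 10 highest genes. As the labels name an mRNA preparation kit, counts of ribosomal and other non-coding RNA need not give their level in the animals.

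Oocyte and yolk transcripts were abundant in these animals and sperm transcripts were scarce. The 6 vitellogenin genes, whose products carry yolk from the intestine to the oocytes, had a median of 2295 ± 33.98 RPKM and took 7.86% ± 0.092 of all counts. Their levels ran from vit-1 at 262 ± 2.33 RPKM and the near-identical vit-4 (411 ± 14.3 RPKM) and vit-3 (455 ± 13.6 RPKM) up to vit-6. All 28 oocyte and germline genes were detected, with a median of 444 ± 6.72 RPKM; the eggshell proteoglycan genes cpg-2 (1731 ± 65.7 RPKM) and cpg-1 (1486 ± 58.1 RPKM) were highest and the synaptonemal complex gene syp-1 lowest (44.7 ± 0.398 RPKM). Of 50 sperm genes only 7 were detected, with a median of 0.60 ± 0.0892 RPKM; spe-44, a transcription factor gene of the sperm programme, was highest at 13.5 ± 0.112 RPKM and spe-9 lowest at 0.260 ± 0.0778 RPKM. Both high lists lay at percentile 100 of the random lists and the sperm list at 0.16. Of the 50 sperm genes, 31 are msp genes, whose near-identical copies have uncertain counts, and 1 of these was detected. Oocyte and germline genes exceeded sperm genes by 8.26 ± 0.068 on the log2 scale (28 and 50 genes, permutation p = 1e-05, adjusted p = 2.8e-05, higher in 2 of 2 libraries). The size of that difference rests partly on the msp genes, and it was 6.08 among members with at least 1 RPKM. Oocyte and germline genes exceeded the early embryonic zygotic genes by 6.89 ± 0.039 (28 and 20 genes, permutation adjusted p = 2.8e-05, 2 of 2 libraries). The zygotic list had 14 of 20 genes detected at a median of 3.84 ± 0.239 RPKM (percentile 11.2), led by lin-26 (72.1 ± 1.09 RPKM) and nhr-2 (18.6 ± 0.201 RPKM), with sdz-38 lowest (0.523 ± 0.0064 RPKM).

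Adult cuticle collagens had a higher median than moulting genes, but abundant and scarce collagens occurred both on and off the adult list. The highest collagens, col-106 and col-95, are not on it. Adult cuticle collagens had a median of 85.7 ± 4.53 RPKM over 9 detected genes of 11 (percentile 99.9, but inside the random lists with CPM in place of RPKM), with col-122 at 488 ± 3.76 RPKM, col-140 at 256 ± 5.10 RPKM and col-119 at 255 ± 0.898 RPKM, while col-120 was lowest at 0.682 ± 0.519 RPKM. Moulting and larval cuticle genes had a median of 1.73 ± 0.789 RPKM over 22 of 24 genes (percentile 0.25); nhr-23, a nuclear receptor gene of the moulting programme, was highest at 20.7 ± 0.427 RPKM, followed by sqt-3 at 14.2 ± 3.26 RPKM, and bli-1 was lowest at 0.412 ± 0.294 RPKM. The adult list exceeded the moulting list by 3.41 ± 0.190 on the log2 scale (11 and 24 genes, permutation p = 0.0001, adjusted p = 0.000233, 2 of 2 libraries). Of all 156 col genes, 81 were detected at a median of 2.67 ± 0.893 RPKM (percentile 0), from col-146 at 0.549 ± 0.294 RPKM to col-95 (606 ± 37.3 RPKM) and col-106 (610 ± 13.8 RPKM). Vitellogenins exceeded the collagens by 8.68 ± 0.210 on the log2 scale (6 and 156 genes, permutation adjusted p = 2.8e-05, 2 of 2 libraries).

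Among tissue markers, those of neurons were below the random lists with RPKM but not with CPM, and those of muscle were inside them with RPKM but above them with CPM. Intestinal genes were inside them with both. Neuronal genes had a median of 2.70 ± 0.611 RPKM over 27 of 30 genes (percentile 1.89), ranging from eat-4, the vesicular glutamate transporter gene (0.277 ± 0.0012 RPKM), to egl-21 (24.5 ± 0.393 RPKM) and snb-1, the synaptobrevin gene (189 ± 12.5 RPKM). The 20 intestinal genes had a median of 15.4 ± 0.107 RPKM (percentile 65.7), led by the cathepsin B-like protease genes cpr-1 (840 ± 41.9 RPKM) and cpr-6 (740 ± 35.3 RPKM), with end-3 lowest (0.609 ± 0.039 RPKM). The 21 muscle genes had a median of 30.04 ± 3.88 RPKM (percentile 93.8), led by act-4 (256 ± 6.19 RPKM) and mlc-2 (191 ± 3.80 RPKM), with the giant titin-like gene ttn-1 lowest (0.524 ± 0.0935 RPKM). Neuronal minus intestinal genes was -2.75 ± 0.012 on the log2 scale (30 and 20 genes, permutation p = 0.00016, adjusted p = 0.00032, lower in 2 of 2 libraries). Intestine and muscle differed by 0.19 ± 0.052 (20 and 21 genes, permutation adjusted p = 0.815), a difference that did not pass and turned to -0.70 without division by gene length.

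Genes for making and clearing protein and for respiration were expressed far above the typical gene, whose median was 10.96 RPKM. Cytosolic ribosomal protein genes had a median of 1358 ± 44.4 RPKM over 75 of 76 genes and took 6.39% ± 0.194 of counts, with rpl-24.2 lowest (87.2 ± 11.3 RPKM). The 33 proteasome genes had a median of 221 ± 2.1 RPKM, from rpn-6.2 (7.70 ± 0.141 RPKM) to pas-5 (294 ± 8.91 RPKM) and pbs-1 (383 ± 7.95 RPKM). Ribosomal protein genes exceeded proteasome genes by 2.48 ± 0.033 on the log2 scale (76 and 33 genes, permutation adjusted p = 2.8e-05, 2 of 2 libraries). Nuclear genes of oxidative phosphorylation had a median of 195 ± 4.24 RPKM over 35 genes (185 and 191 RPKM in replicates 1 and 2), with the ATP synthase genes atp-2 (1022 ± 0.933 RPKM) and atp-1 (888 ± 13.9 RPKM) highest and ucr-2.2 lowest (27.9 ± 0.0068 RPKM). Mitochondrially encoded subunits had a median of 144 ± 22.6 RPKM over 11 of 12 genes, led by COX1 (1637 ± 41.2 RPKM) and COX3 (1016 ± 2.98 RPKM), with ND6 lowest (11.6 ± 3.12 RPKM). All 4 lists lay at percentile 100. The nuclear and mitochondrial subunits differed by 0.44 ± 0.179 (35 and 12 genes, permutation adjusted p = 0.552), which did not pass and changed sign to -0.14 among members with at least 1 RPKM.

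Heat-inducible chaperone transcripts were scarce beside the housekeeping chaperones, though the detected ones lay inside the random lists. Of 9 inducible heat shock genes 4 were detected, hsp-16.2 at 2.33 ± 0.752 RPKM, hsp-16.48 at 2.13 ± 0.708 RPKM, hsp-16.41 at 1.98 ± 0.220 RPKM and hsp-70 at 1.78 ± 0.152 RPKM (median of their mean RPKM 2.05, medians of 1.81 and 2.01 RPKM in replicates 1 and 2, SD 0.142, percentile 10.1). The 14 constitutive cytosolic chaperone genes had a median of 162 ± 0.347 RPKM (percentile 100), with the HSP70 gene hsp-1 at 1581 ± 2.43 RPKM, hsp-90 at 1102 ± 38.9 RPKM and the chaperonin gene cct-3 lowest at 80.2 ± 2.27 RPKM. The inducible minus the constitutive list was -7.03 ± 0.0045 on the log2 scale (9 and 14 genes, permutation adjusted p = 2.8e-05, 2 of 2 libraries). As the hsp-16 pairs have uncertain counts, the size of that difference is uncertain too. It was -6.14 among members with at least 1 RPKM. Genes of the mitochondrial unfolded protein response had a median of 47.9 ± 1.81 RPKM (13 genes, percentile 98.6), with hsp-6 at 231 ± 10.1 RPKM, hsp-60 at 176 ± 1.08 RPKM and dve-1 lowest at 2.3 ± 0.240 RPKM. Those of the endoplasmic reticulum response had a median of 99.1 ± 2.90 RPKM (20 genes, percentile 100), with the calreticulin gene crt-1 at 662 ± 0.731 RPKM, pdi-3 at 488 ± 11.4 RPKM and atf-6 lowest at 9.19 ± 0.0184 RPKM. The 2 responses differed by -1.02 ± 0.019 on the log2 scale (13 and 20 genes, permutation adjusted p = 0.149), which did not pass.

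Detoxification, immune and longevity gene lists held both very abundant and very scarce members. DAF-16 target genes had a median of 20.3 ± 1.15 RPKM (21 of 22 genes, percentile 79.7); sip-1 was highest, the metallothionein gene mtl-1 reached 458 ± 76.9 RPKM, the mitochondrial superoxide dismutase gene sod-3 was at 2.59 ± 0.0195 RPKM and sod-5 was lowest at 0.916 ± 0.149 RPKM. SKN-1 detoxification genes had a median of 30.1 ± 0.246 RPKM (17 of 20 genes, percentile 92.3), with gst-7 at 212 ± 7.55 RPKM, the glutathione reductase gene gsr-1 at 100.02 ± 3.41 RPKM, gst-4 at 20.2 ± 2.04 RPKM and gst-30 lowest at 0.623 ± 0.0224 RPKM. The SKN-1 and DAF-16 lists differed by -0.46 ± 0.029 (20 and 22 genes, permutation adjusted p = 0.642), which did not pass. Antimicrobial genes had a median of 26.9 ± 3.91 RPKM (45 of 48 genes, percentile 96.8), led by the lysozyme gene lys-7 (1191 ± 47.7 RPKM) and the saposin-like gene spp-5 (1073 ± 105 RPKM), with clec-4 lowest (0.393 ± 0.0657 RPKM). Antioxidant enzymes had a median of 21.2 ± 0.427 RPKM (22 of 23 genes, percentile 81.5), led by the peroxiredoxin gene prdx-2 (629.7 ± 29.01 RPKM) and sod-1 (267 ± 27.7 RPKM). The antimicrobial and antioxidant lists differed by 0.56 ± 0.043 (48 and 23 genes, permutation adjusted p = 0.547), which did not pass. The 29 insulin, TOR and longevity regulators had a median of 37.3 ± 1.15 RPKM (percentile 99.1). The Rieske iron-sulfur protein gene isp-1 was at 196 ± 6.80 RPKM. The insulin receptor gene daf-2 was at 51.9 ± 2.38 RPKM, daf-16 at 29.7 ± 2.42 RPKM, and eat-2 was lowest at 0.403 ± 0.0593 RPKM.

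Fat synthesis genes and both propionate lists lay above the random lists, and fat breakdown genes did not. The 19 fat synthesis genes had a median of 69.2 ± 9.06 RPKM (percentile 99.95 of the random lists), led by the fatty acid desaturase genes fat-2 (666 ± 29.4 RPKM) and fat-1 (383 ± 9.72 RPKM), with fat-6 at 67 ± 4.36 RPKM, fat-7 at 44.5 ± 2.32 RPKM and dgat-2 lowest at 5.67 ± 0.642 RPKM. The 24 fat breakdown genes had a median of 18.3 ± 1.69 RPKM (percentile 75.2), from fil-1 (0.591 ± 0.0998 RPKM) to ech-6 (171 ± 2.5 RPKM) and the lipase gene lipl-5 (242 ± 9.56 RPKM). Synthesis exceeded breakdown by 2.08 ± 0.033 on the log2 scale (19 and 24 genes, permutation p = 0.00161, adjusted p = 0.00282, 2 of 2 libraries). All 5 genes of the propionate shunt, the route that burns propionate when vitamin B12 is short, were detected. They were alh-8 (516 ± 13.3 RPKM), acdh-1 (318 ± 4.62 RPKM), ech-6, hphd-1 (126 ± 1.82 RPKM) and hach-1 (109.8 ± 4.67 RPKM), with a median of 171 ± 2.5 RPKM (percentile 99.9). The canonical propionate and methionine cycle list had a median of 71.2 ± 2.18 RPKM (14 genes, percentile 99.98), led by ahcy-1 (868 ± 0.682 RPKM) and mel-32 (289 ± 9.37 RPKM), with cbs-2 lowest (0.356 ± 0.0562 RPKM). The shunt lay 1.97 ± 0.016 above the canonical list (5 and 14 genes, exact permutation p = 0.0753, adjusted p = 0.117), which did not pass. Autophagy and lysosome genes had a median of 46.3 ± 1.99 RPKM (25 genes, percentile 99.7), with the cathepsin L gene cpl-1 at 713 ± 3.08 RPKM, lgg-1 at 402 ± 21.6 RPKM and lmp-2 lowest at 1.76 ± 0.0422 RPKM.

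C-type lectins, nuclear hormone receptors, cytochrome P450s and UDP-glucuronosyltransferases sat at low levels, while the detected histone genes lay inside the random lists. C-type lectins had 90 of 240 genes detected at a median of 2.63 ± 0.0507 RPKM (percentile 0.01), yet clec-87 reached 1644 ± 0.0483 RPKM and clec-91 reached 469 ± 0.201 RPKM. Nuclear hormone receptors had 165 of 269 detected at a median of 1.63 ± 0.0115 RPKM (percentile 0), with nhr-49, a regulator of fat metabolism, highest at 51.5 ± 0.0938 RPKM and nhr-66 next at 43.4 ± 0.174 RPKM. Cytochrome P450 genes (60 of 74 detected) had a median of 3.14 ± 0.181 RPKM (percentile 0.39), led by cyp-31A2 (83.5 ± 2.82 RPKM) and its near-copy cyp-31A3 (62.1 ± 1.43 RPKM). UDP-glucuronosyltransferases (56 of 67 detected) had a median of 2.68 ± 0.0462 RPKM (percentile 0.13), led by ugt-22 (43.6 ± 0.92 RPKM) and ugt-63 (37.1 ± 1.08 RPKM). Histone genes had 24 of 72 detected at a median of 7.53 ± 0.189 RPKM (percentile 31.6), and medians of 7.16 and 7.43 RPKM in replicates 1 and 2, led by his-72 (422 ± 23.3 RPKM) and his-74 (279.8 ± 20.5 RPKM). Of the 72 genes, 30 had no counts in either library, and the median over all 72 was 0.126 RPKM. As core histone copies also have uncertain counts, these values do not give the level of histone transcripts as a whole. In all, 16 of the 34 lists lay above the random lists and 8 below. The high lists include ribosomal RNA, with 2 of 20 genes detected, whose counts after an mRNA preparation need not give its level. The medians of the low lists describe detected members only, and with undetected members kept the moulting, neuronal, P450 and glucuronosyltransferase lists were not under the median of all protein-coding genes.

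**Figure D1:**
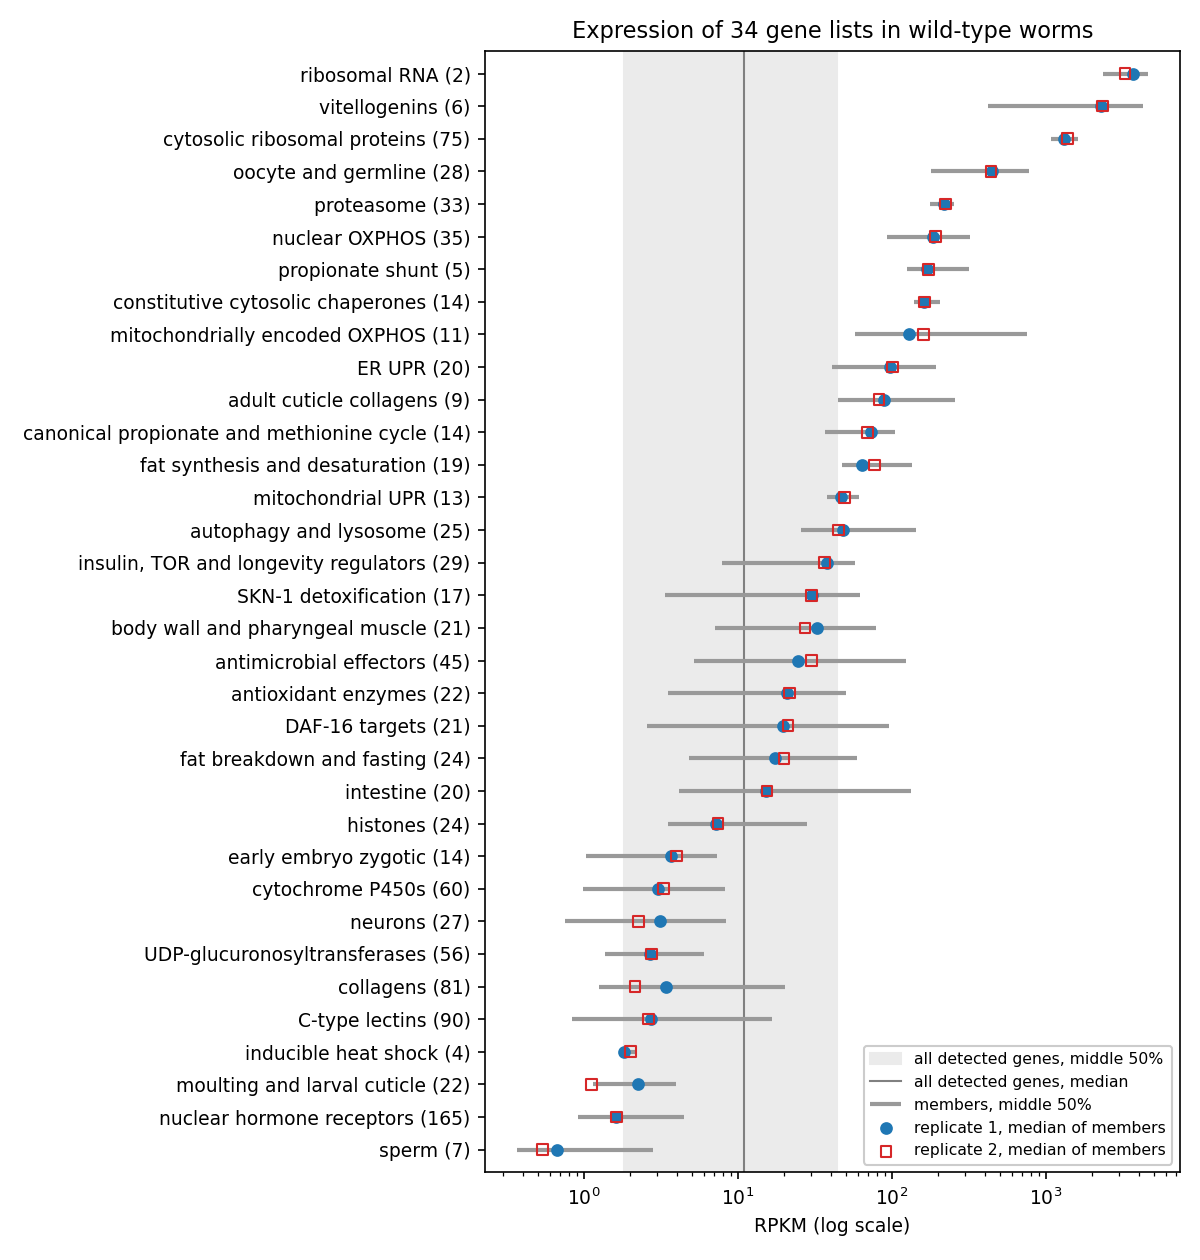
Median RPKM (log scale) of the detected members of each of 34 gene lists in replicate 1 (filled circles) and replicate 2 (open squares), with the number of detected genes in parentheses, grey bars for the middle 50% of members, and the vertical line and band for the median and middle 50% of all 12757 detected genes. Vitellogenins (2295 RPKM), ribosomal proteins (1358 RPKM) and germline genes (444 RPKM) lay far to the right of the background median of 10.96 RPKM, and sperm genes (0.60 RPKM) far to the left.

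Between the libraries, cuticle genes were lower in replicate 2 and several short non-coding RNAs were higher. Of 14397 genes tested, 109 passed the threshold, 32 higher and 77 lower in replicate 2. Collagens named col made up 31 of the lower genes, out of 116 col genes tested, and none passed in the other direction. Adjusted over the list alone, 32 passed. The median log2 ratio of the col genes was -0.55, below all 10000 expression-matched random lists, and 95 of 116 lay below 0. Families that include further collagen genes also had calls, all of them lower: bli (3), dpy (3), rol (3) and sqt (1). The 31 is therefore not the count of all collagens among the lower genes. The moulting and larval cuticle list had 7 lower and 0 higher of 23 tested (7 when adjusted over the list alone), a median of -0.56 and 22 of 23 below 0. It is not a group apart from the collagens, since 12 of the 23 are collagen genes (median -1.02) and all of the 7 but qua-1 are among them. The other 11 had a median of -0.42.

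Named cuticle genes lower in replicate 2 were col-73 (169 and 37 counts in replicates 1 and 2, log2 ratio -2.33, 95% interval -2.90 to -1.83), dpy-13 (190 and 55 counts, log2 ratio -1.94, interval -2.41 to -1.51) and the adult cuticle collagen col-120 (30 and 10 counts, log2 ratio -1.70, interval -2.94 to -0.67). At 0 counts in replicate 2, set at the floor of 3 counts, col-88 (23 counts in replicate 1) was 8.56-fold lower. On the same floor bli-2 of the moulting list (14 counts) was 5.21-fold lower. Their 95% intervals reached up to log2 ratios of -2.68 for col-88 and -1.89 for bli-2, so smaller folds lie within counting error. The cuticle gene rol-1 was at 2.84 CPM in replicate 1 and 0.128 CPM in replicate 2. Other lower genes with a mean of at least 100 counts were grl-16 (log2 ratio -1.52), ZK180.5 (-1.23), F41F3.3 (-1.21), abu-14 (-1.20) and ram-2 (-1.09). The loss was larger among scarce collagens: the 87 with under 300 counts in the sum had a median of -0.90 and included all 31 calls. The 29 with at least 300 counts had a median of -0.07 and no call. With at least 100 counts, 54 collagens had a median of -0.17 (percentile 0). The cut at 300 counts was not fixed beforehand, and the difference across it was not tested. The share of counts in all col genes was 0.468% in replicate 1 and 0.459% in replicate 2. Adult cuticle collagens had a median of -0.12 over 9 genes (percentile 0.06), with 1 gene called lower and 0 higher. That median was -0.11 (percentile 0.03) with rescaled RPKM and -0.18 (percentile 0) with the length trend removed. Deposited RPKM, whose read totals change with the row number, gave 0.016 (percentile 4.29, inside the random lists) and moved the median of all genes to 0.13.

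Higher in replicate 2 were the 5.8S ribosomal RNA gene rrn-2.1 (1744 and 9505 counts, log2 ratio 2.29, interval 2.21 to 2.36) and the non-coding RNA genes C36C9.10 (234 and 1668 counts, log2 ratio 2.67, interval 2.48 to 2.88) and T21B4.21 (57 and 236 counts, log2 ratio 1.88, interval 1.47 to 2.33). The protein-coding genes F56D6.8 (1.06), C18D11.6 (1.02), and F15E6.4 (1.01) also passed, at the log2 ratios given, as did F23A7.4 (13.03 and 26.3 CPM). Each of these named genes spans under 500 nucleotides. Protein-coding genes with up to 500 nucleotides of exon were higher in replicate 2 as a class, with a median log2 ratio of 0.18. How much of the named differences goes with length was not tested. Of the 32 higher genes, 22 were protein-coding, 5 were annotated as ncRNA, 2 as snoRNA, 2 as lincRNA and 1 as rRNA, whereas all 77 lower genes were protein-coding. After an mRNA preparation, differences in ribosomal and other non-coding RNA between the libraries need not be differences in the animals. The ribosomal RNA rrn-3.1 went the other way, from 688425 to 496006 counts, and the share of counts in ribosomal RNA genes was 2.45% in replicate 1 and 1.62% in replicate 2. No member of the vitellogenin, germline or sperm lists passed, and the medians of those lists (0.03, -0.04 and -0.16) lay within the range of the random lists. With the length trend described below subtracted, vitellogenins lay above the random lists (0.08, percentile 99.95, 6 of 6 genes above 0) and germline genes below them (-0.04, percentile 0.34).

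**Figure D2:**
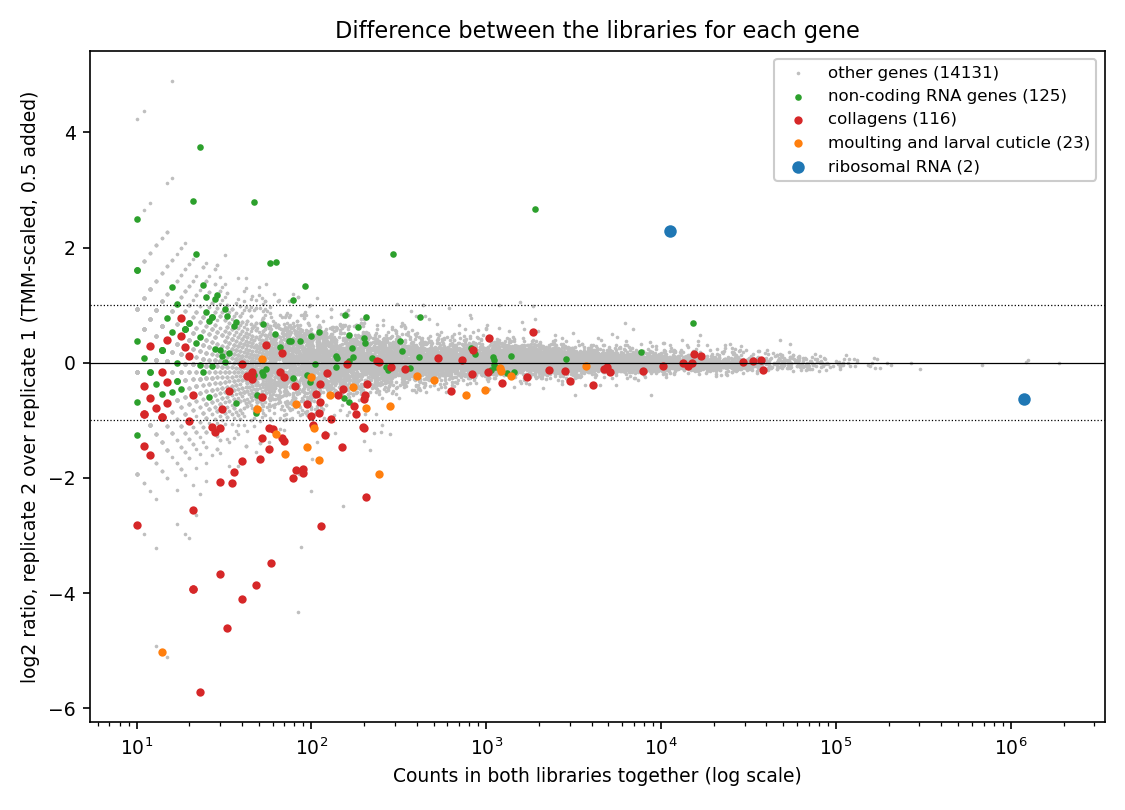
Log2 ratio of replicate 2 over replicate 1 (TMM-scaled, 0.5 added to each count) against the counts of both libraries together (log scale) for 14397 genes, with collagens in red, moulting and larval cuticle genes in orange, non-coding RNA genes in green, ribosomal RNA genes in blue and dotted lines at 2-fold. Scarce collagens lay below 0 while abundant ones lay near 0, and rrn-2.1 (2.29) was the only gene past the threshold among those with at least 10000 counts.

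Short genes were higher in replicate 2 and long genes were lower, by small amounts. Among 9732 protein-coding genes with at least 100 counts in the sum, the log2 ratio fell with annotated exon length (Spearman rho -0.39 across genes). Its median was 0.18 for 505 genes of up to 500 nucleotides, 0.02 for 4125 genes of 1000 to 2000 nucleotides and -0.09 for 356 genes over 5000 nucleotides. Cytosolic ribosomal proteins had a median of 0.07 (75 genes, percentile 100; -0.040 once the length trend was subtracted), nuclear oxidative phosphorylation genes 0.05 (35 genes, percentile 99.99; -0.0031 after subtraction) and antimicrobial genes 0.06 (47 genes, percentile 98.5; -0.021 after subtraction). Proteasome genes had a median of 0.03 (33 genes, percentile 99.3), which went to 0.0016 (percentile 45.5, inside the random lists) after subtraction. Mitochondrially encoded subunits had a median of 0.31 (11 genes, percentile 100), with ND2 at 23.3 and 46.4 RPKM in replicates 1 and 2, whereas COX1 was at 1666 and 1608 RPKM and the list's share of counts was 0.547% and 0.555%. Fat synthesis (0.08), fat breakdown (0.10) and ribosomal RNA genes (0.83, from 2 genes that moved in opposite directions) were also above the random lists, before and after subtraction. With deposited RPKM the fat synthesis (percentile 94.8), fat breakdown (90.5), nuclear oxidative phosphorylation (92.7), proteasome (89.2), antioxidant (95.7) and antimicrobial (56.1) lists all fell inside the random lists. Those values use read totals that change with the row number, so they decide little between the libraries. With rescaled RPKM the same lists, in that order, stayed above the random lists (percentiles 99.99, 99.9, 99.99, 99.3, 99.2 and 97.7). Antioxidant genes were above them before (0.09, percentile 97.7) and inside them after subtraction (0.06, percentile 97.1). Muscle genes were below the random lists (-0.08, percentile 0), after subtraction (percentile 0.02) and with deposited RPKM (0.036, percentile 0.8, where the median of all genes was 0.13) as well. The insulin, TOR and longevity list was below them (-0.05, percentile 0.605), also with rescaled RPKM (-0.041, percentile 0.58). It was inside them after subtraction (-0.0046, percentile 35) and with deposited RPKM (0.084, percentile 6.98). No member of the protein-coding lists in this paragraph passed the 2-fold threshold. In all, 9 lists were above and 5 below the random lists. With an assumed coefficient of variation of 0.2, which allows for spread beyond counting noise, 14 genes differed, 2 higher and 12 lower.

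**Figure D3:**
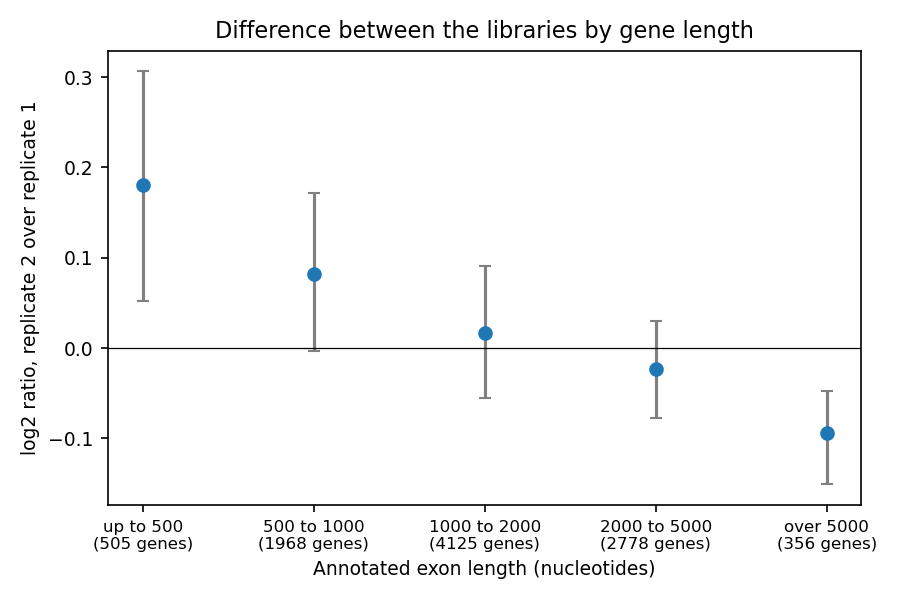
Median log2 ratio of replicate 2 over replicate 1 (points) with the middle 50% of genes (bars) by annotated exon length, for 9732 protein-coding genes with at least 100 counts in the sum. The median went from 0.18 in the shortest genes to -0.09 in the longest.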

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

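All tests in this part were chosen after the deposited values were seen. The read totals behind the deposited RPKM drew attention because they lie outside the counts compared here: of the 8 found, 6 matched neither library, and where they come from was not tested. Division of each library by its own total was argued against, since only 12.5% of rows used it. A vector of 8 read totals repeated down the rows is a candidate explanation: at a period of 8 rows, 100% of 5766 genes lay within 0.1% of their row class, while at periods of 7 and 9 rows the spread within a class stayed at 13.4%. Which software step did this stays open, and no biological explanation was tested, as the pattern follows the row number. Between row classes, the ratio of the total used for replicate 1 to that used for replicate 2 ran from 0.787 to 1.27, so deposited RPKM of the same gene cannot be compared between the libraries without rescaling.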

How the results depend on the processing

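The rescaled RPKM used for list and pair levels was itself chosen after the data were seen. It replaced the planned deposited RPKM, which became the alternative there. Other alternatives chosen after the data were seen were the rescaled RPKM for list shifts, undetected members kept and the length trend removed. The remaining ones were fixed beforehand. Leaving out either replicate is not possible for results between the libraries, and no paired analysis was possible because there was 1 group. The same 8 list pairs passed under every setting tried. In replicate 1 alone neurons were not among the low lists, and in replicate 2 alone antimicrobial genes were among the high ones (log2 over the background, list level: neurons -1.45, list level: antimicrobial effectors 1.55). Without a filter on low counts Spearman's rho was 0.980, and with a background of genes with at least 1 count 4 lists were low, as moulting genes, neurons, P450s and glucuronosyltransferases came inside the random lists, while muscle and antimicrobial genes became high. With CPM, neurons were no longer low, adult cuticle collagens no longer high, and muscle became high. With means of log2 values, intestine and antimicrobial genes became high and early embryonic genes low. With undetected members kept, log2 levels over the background turned for moulting genes (0.029), neurons (0.47), ribosomal RNA (-1.26), P450s (0.0015) and glucuronosyltransferases (0.29). Collagens were then no longer low, inducible heat shock genes and histones became low, and muscle, intestine, antimicrobial, antioxidant, SKN-1, DAF-16 and fat breakdown genes became high. Among members with at least 1 RPKM, nuclear minus mitochondrial oxidative phosphorylation became -0.14 and SKN-1 minus DAF-16 0.0013, and with CPM intestine minus muscle became -0.70; none of the 3 passed in any setting. The cause was not tested.

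The 109 calls (32 higher, 77 lower) became 31 (8 and 23) with at least 100 counts, where fewer genes were tested, 1618 (926 and 692) without a fold minimum, 202 (85 and 117) at 1.5-fold, 43 (9 and 34) with an assumed coefficient of variation of 0.1 and 14 (2 and 12) with 0.2. Library totals gave 111 calls, DESeq2 size factors 110, and no count filter 30 higher and 74 lower. With deposited RPKM the median of all genes moved from 0.01 to 0.13, 4 lists were higher in replicate 2 (ribosomal proteins, mitochondrially encoded subunits, ribosomal RNA and, newly, DAF-16 targets), neurons were newly lower, and adult cuticle collagens (0.016, percentile 4.29), muscle (0.036, percentile 0.8) and the insulin, TOR and longevity list (0.084, percentile 6.98) changed sign with that shift of all genes; of these, muscle stayed below the random lists. DAF-16 targets were also higher with rescaled RPKM, which changed the call of no other list, and intestinal genes were lower with at least 100 counts. With the length trend removed 9 lists were lower (newly ribosomal proteins, germline genes, intestine, histones and C-type lectins), vitellogenins, P450s and endoplasmic reticulum response genes were newly higher, proteasome, antioxidant and insulin, TOR and longevity genes came inside the random lists, and ribosomal proteins (-0.040), nuclear oxidative phosphorylation (-0.0031) and antimicrobial genes (-0.021) turned negative. With deposited RPKM for levels, 55 single-gene levels moved by more than the spread between the libraries. The 103 values that did not change include lists and pairs, which were judged by percentile or p instead. Depth limits the comparison: of 109 calls, 78 had under 100 counts in the sum, 17 had 1 to 3 counts in a library and 7 had none.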

Other observations

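Gene-name families with most members outside the fixed lists, chosen after their levels were seen, are given here for the high and low ends of their ranking. Of 175 families with at least 8 detected genes, 39 lay above and 39 below random lists of the same size. The 8 mcm genes of the replicative helicase family had a median of 205 RPKM, with mcm-7 at 334 ± 4.60 RPKM. Digestive and lysosomal protease families were also high, with cpr genes at a median of 182 RPKM and asp genes at 162 RPKM, led by asp-6 (792 ± 20.4 RPKM). Next came cox genes of cytochrome c oxidase (152 RPKM), rsp genes of splicing factors (133 RPKM), ndub genes of respiratory complex I (132 RPKM) and rpb genes of RNA polymerase II (129 RPKM).

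Few chemoreceptor genes were detected, and the guanylate cyclase and neuropeptide receptor families lay below the random lists (percentile 0 for both). Among neuropeptide genes, flp genes had 30 of 31 detected at a median of 4.65 RPKM (percentile 10.1, inside the random lists) and nlp genes 55 of 71 at 4.25 RPKM (percentile 3.34, inside them), with nlp-40 at 93.5 ± 3.77 RPKM. Of 1309 genes with chemoreceptor family names, 26 were detected and 660 had no counts in either library; the highest, str-176, was at 5.23 ± 0.143 RPKM. Guanylate cyclase genes (gcy) had a median of 0.342 RPKM over 15 detected genes, and the neuropeptide receptor family npr 0.573 RPKM over 24. Insulin-like peptide genes had 19 of 38 detected at a median of 1.95 RPKM, although ins-19 reached 141.8 ± 36.1 RPKM. F-box genes of the fbxa and fbxb families had medians of 1.45 and 1.07 RPKM.

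Tests in the paragraphs below were chosen after the differences between the libraries were seen, except that those of the length trend on ribosomal and respiratory genes were written before their values were computed. Collagens were lower in replicate 2, and the design gives no biological contrast, so no biological explanation from the groups was tested. A length bias was argued against by its direction. Removing the length trend moved the collagen median from -0.55 to -0.57, still below all random lists, so the trend ran opposite to the collagen shift. With a trend in that direction, the subtraction itself left little room for another outcome. The 11 moulting genes that are not collagens, among them mlt-8, mlt-11, nas-37 and ptr-4, had a median of -0.44 with the trend removed, below all random lists. Low values of that list had been seen before the test and left it little room to come out otherwise, so a larger share of moulting animals in replicate 1 stays open. Fourth-stage larvae that were making sperm remain a candidate source too, as the 31 major sperm protein genes together had 83 counts in replicate 1 and 31 in replicate 2 (log2 ratio -1.58, 95% interval -2.22 to -0.97). Single sperm genes went both ways. In replicates 1 and 2, ssq-1 was at 0.497 and 1.31 CPM. It passed the threshold as higher in replicate 2 (14 and 41 counts, log2 ratio 1.36, 95% interval 0.49 to 2.38). One of the 31, msp-31, the only msp gene with enough counts to be tested alone, was at 0.391 and 0.480 CPM. The others were spe-44 at 21.9 and 22.1 CPM, ssp-10 at 2.06 and 1.69 CPM and spe-9 at 0.639 and 0.416 CPM. The 9 sperm genes that could be tested, of 50, had a median of -0.16, within a wide range of random lists (-0.37 to 0.36), which decides little; whether such animals were in the culture stays open.

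Ribosomal protein and respiratory genes were slightly higher in replicate 2, and the fixed lists could not show whether this concerned their function or their length. With the length trend removed, the nuclear oxidative phosphorylation median was -0.0031, within the range of random lists, so a length bias between the libraries may account for its higher median. The ribosomal protein median was -0.040, below all random lists. That met neither of the outcomes written beforehand (within their range, or still above it), so whether length is the source of the ribosomal shift stays open. Length was argued against for the mitochondrially encoded subunits, whose median stayed at 0.28, above all random lists. What set those transcripts apart stays open, and no biological explanation was tested.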
